A study of Homo sapiens with 2 samples.

How the data were processed

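Total RNA of MCF7 cells, isolated with a column kit that keeps small RNA, was labelled with the dye Cy5 and hybridised to Toray 3D-Gene miRNA arrays, a single-colour platform, per the labels' protocols. The series holds 1 array per condition, each with 3200 spots. 15 of the 2555 human miRNA probes carry several miRNA names each. The array has no unit of sequencing depth, and its precision is limited by the number of arrays.

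Per the file headers, the scanner files hold the median intensity of each spot at the red channel and a background median, from 3 scans at different gains. How the scans were joined, the image software and its version are not given in the sources used here. The deposited value table holds intensity values scaled by the authors, and its processing was worked out from the values. On each array it is an exact straight line of the spot median (largest residual 5.81e-05 and 3.85e-05) that crosses 0 at the mean of the blank spots and is scaled so that the median of the values given is 25. The table gives values for 1552 and 1616 miRNAs and leaves out those whose spot lies under 39.3 units on the not induced array and under 38.6 on the induced array. Its direction and linear scale are therefore known, and it is not centred per miRNA. The median over miRNAs with a value on both arrays is 30.5 in the not induced and 34.5 in the induced column.

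The background column of the scanner files rises with the spot. Among miRNAs with spots of 300 to 1000 units the background lay above the spot itself for 70.0% on the not induced array and 36.0% on the induced array, while blank spots had a background median of 19.1 and 26.1. It was therefore not used as a local background, although correction with it had been the plan. This was decided from the behaviour of the column before any ratio was computed. Ratios under both backgrounds and offsets of 50 and 10 were then looked at before the other steps were settled. The background was taken instead as the mean of the 229 blank spots after leaving out the highest and lowest 5% (37.0 units, SD 1.16, not induced; 36.2 units, SD 1.26, induced), and the planned correction was kept as an alternative.

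The main values were made in R 4.3.3 with limma 3.58.1: background correction by normexp with an offset of 50 on all spots, human miRNA probes only, log2, and quantile normalisation between the arrays. A ratio on this scale understates the change of dim miRNAs. A miRNA was called detected where its spot lay above the blank mean plus 2 SD. Bounds for miRNAs detected on 1 array set the bright value against the higher of the dim probe's own value and the lowest detected value on that array. They take each spot as measured and do not include its error. The error given with a ratio is the SD over 100 redraws of every spot with the scatter of repeated control spots, which was 1.51 and 1.49 units for 21 dim control probes with 8 spots each and 4.90% and 4.38% for 2 spike controls. It covers scatter between spots only, not labelling, hybridisation or culture.

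No test was made because each group is 1 array. Counts are at a fixed 2-fold, and a list's median is described by its percentile among 10000 random lists of the same size, matched on mean level in the same arrays. The miRNA lists, the naming rule and all alternatives but the scaling to spike controls were fixed before the data were examined. The correction with the background column was then the planned main setting, not an alternative. The rule names, among miRNAs detected on both arrays and at or above the lower quartile of level, the 12 largest and 12 smallest ratios; the 3 brightest miRNAs detected on each array alone; a fixed set (miR-205, miR-203, the miR-200 family, miR-34a, miR-34c, miR-130b, miR-193a, miR-221, miR-222, miR-21 and miR-210); and the 2 members of each list with the largest ratio by size. Further members of the lists were named after their values were seen. The spot SD as the error, the central 95% of random lists as the range and the set of the 333 brightest miRNAs were also chosen after the data were seen. The brightest miRNAs keep a ratio of 0 where they hold the same rank on both arrays, since quantile normalisation gives equal ranks equal values. The alternatives were other background corrections, other scalings between the arrays, the deposited values, other detection filters, miRBase entries numbered under 1000 and a 1.5-fold threshold.

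The procedure was tested on simulated data, in which a set of the 2555 miRNAs on a copy of the not induced array was changed by known folds with spot scatter added. Changed miRNAs detected on both simulated arrays numbered 49, 39 and 32 for true folds of 2, 4 and 8. Among them the sign was right for 100% at each fold, and 2.04%, 10.3% and 50.0% passed 2-fold on the offset scale. Dim miRNAs lowered under the detection limit were not scored, so these shares cover raised miRNAs better than lowered ones. None of 947 unchanged miRNAs passed, but the largest ratio among them was 0.55 by size. A ratio of that size can thus arise on this scale without a change. The count of miRNAs past 2-fold on this scale thus misses most dim miRNAs with true changes. Both simulated arrays came from the not induced array, so that no shift between arrays was simulated. The share of right signs therefore does not cover signs that depend on the scaling. Lists and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The labels and file headers name no genome build. Which miRNA genes neighbour each other was taken from a RefSeq gene table of assembly GRCh38.p14, and no coordinates are given.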

Results

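MicroRNAs (miRNAs) were profiled in MCF7, an established luminal breast cancer cell line, that carried a doxycycline-inducible construct for ΔNp63α, the isoform of the transcription factor p63 that lacks the N-terminal transactivation domain and is characteristic of basal epithelial cells. 1 array was hybridised with RNA of cells left without doxycycline (not induced) and 1 with RNA of cells given doxycycline for 48 h (induced). The comparison asks which miRNAs differ in level after ΔNp63α is switched on. Each group is a single array, so no test could be made and no difference here has a replicate check. The array carries no probe for the TP63 messenger RNA, and the induction itself is known from the labels only. Each array held 2555 human miRNA probes of 1 spot each. At the detection limit set by the blank spots, 1538 probes (60.2%) were detected on the not induced array and 1604 (62.8%) on the induced array, with 1330 detected on both and 743 on neither. The median spot of a detected miRNA was 44.2 scanner units on the not induced array and 43.6 on the induced array, against detection limits of 39.3 and 38.7, so most detected miRNAs lay close to the limit. Control spots also passed this limit, so that detection does not exclude nonspecific signal. The 178 spots named No Probe had means of 41.4 and 40.8 units, and Negative Control 3 had means of 43.4 and 42.6. The means of Negative Controls 1 and 2 passed on the induced array only. miR-4454 and miR-7975 were saturated on both arrays and have no measured ratio.

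miR-205-5p, an epithelial miRNA abundant in basal cells that targets ZEB1 and ZEB2, had the largest ratio on the main scale among miRNAs detected on both arrays. Its spot median was 47.0 units on the not induced array and 129 on the induced array, which gave a log2 ratio of 1.03 ± 0.051 (SD of repeated control spots, 1 array per group) on the background-corrected, quantile-normalised scale with an offset of 50. In the authors' deposited values, which have the blank signal subtracted and no offset, it stood at 35.3 and 314, an 8.89-fold difference. Its rank depended on the scaling, and on the main scale miR-937-5p also stood at 1.03. With median scaling miR-205-5p was at 1.13, under miR-1228-5p (1.17), miR-4730 (1.17) and miR-937-5p (1.16). These also stood above it with 75th percentile, no and spike control scaling. The opposite arm of the same hairpin, miR-205-3p, was detected on the induced array only, with 44.7 units against 38.6, and its deposited value of 29.0 was at least 3.59-fold above the lowest value given on the not induced array. On the offset scale this bound was at least 1.10-fold. Neither bound includes spot error, and the mean of Negative Control 3 was 42.6 units on the induced array. The background used here was the mean of the blank spots. With the background column of the scanner files, which had been the planned correction and which rises with the spot itself, the log2 ratio of miR-205-5p was 0.05. At this probe the column stood at 27.6 units on the not induced and 94.6 on the induced array, and the spot exceeded it by 19.4 and 34.0 units.

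Of the 1330 miRNAs detected on both arrays, 2 were at least 2-fold higher in the induced array and 0 were at least 2-fold lower on the offset scale. The pair was miR-205-5p and miR-937-5p, the latter with a log2 ratio of 1.03 ± 0.054 and a 6.08-fold difference in the deposited values. At 1.5-fold, 10 miRNAs were higher and 2 were lower. These counts leave out miRNAs detected on 1 array only, 208 on the not induced and 274 on the induced array. A dim miRNA that fell under the detection limit is thus not counted as lower. The offset compresses the ratios of dim miRNAs. In the deposited values 77 of the same 1330 miRNAs were at least 2-fold higher and 16 at least 2-fold lower. The authors' values are scaled on each array by the median of the values given, not between the arrays over the same miRNAs. Their median log2 ratio was 0.21 over the miRNAs detected on both arrays and 0.35 over the brightest 333 of these. Deposited folds thus include a shift between the arrays, which was larger for bright miRNAs. With the planned background column 4 miRNAs were at least 2-fold higher (miR-1246, miR-6765-3p, miR-4723-5p and miR-6089) and 4 at least 2-fold lower (miR-1260b, miR-187-5p, miR-4497 and miR-23a-3p), and neither miR-205-5p nor miR-937-5p was among them. Of these 8, all but miR-1246 and miR-187-5p were named after their values were seen. In 4 of the 8 the spot lay under the column on 1 array (miR-1246 and miR-6089 not induced, miR-23a-3p and miR-1260b induced), so these calls rest on a signal not above that background. Of all 1330 miRNAs, 114 had a spot under the column on at least 1 array.

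The other miRNAs among the 12 largest ratios were miR-4730 (log2 ratio 0.98), miR-1228-5p (0.93), miR-1246 (0.90), miR-3940-5p (0.77), miR-5787 (0.69), miR-3665 (0.62), miR-3663-3p (0.59), miR-22-3p (0.59), miR-27a-3p (0.57) and miR-6860 (0.57). miR-1246, whose sequence overlaps U2 small nuclear RNA, was the brightest of them, with a spot median of 817 units on the not induced array and 1946 on the induced array and a 2.35-fold difference in the deposited values. miR-22-3p was 2.40-fold higher in the deposited values, and its opposite arm, miR-22-5p, had a log2 ratio of 0.18 on the offset scale, 3.31 spot SDs above 0. miR-27a-3p, which is transcribed together with miR-23a and miR-24, was 2.22-fold higher in the deposited values. 8 of these 12 are miRBase entries numbered 1000 or more, as were 66.3% of the 997 miRNAs from which they were drawn. All 12 stayed higher under 5 other scalings and 3 other background settings, but not with the planned background column, where miR-937-5p (-0.02), miR-3665 (-0.07) and miR-22-3p (-0.16) fell below 0, as did miR-5787, whose spot lay under the column on 1 array.

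**Figure D1:**
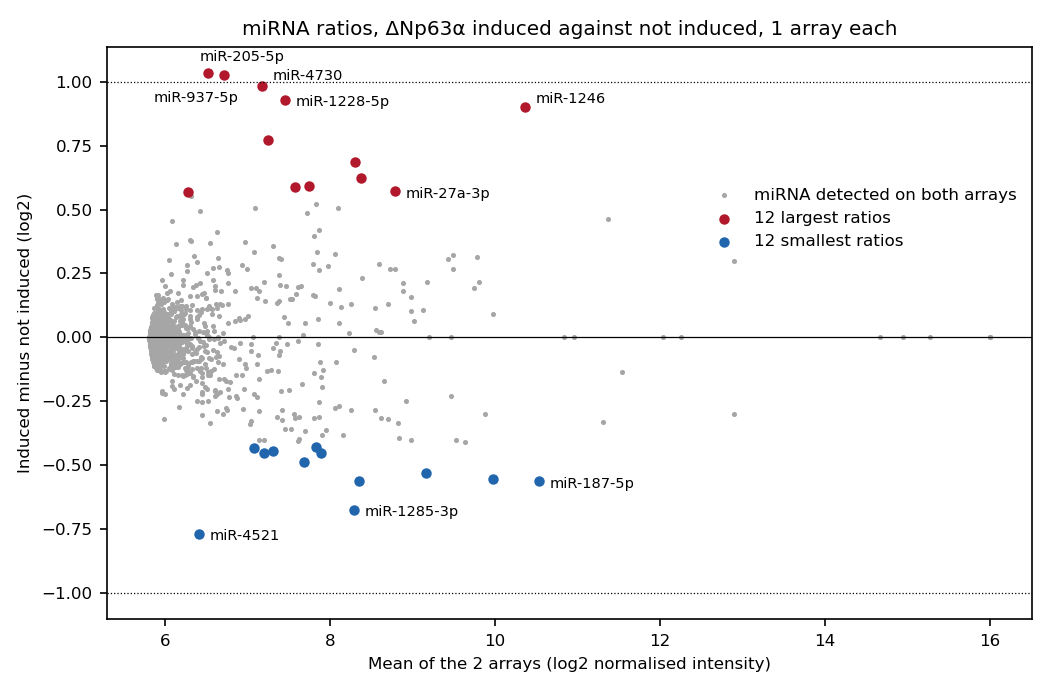
Log2 ratio of the induced over the not induced array (vertical axis) against the mean log2 normalised intensity of both arrays (horizontal axis) for the 1330 miRNAs detected on both arrays; each point is 1 miRNA, coloured points are the 12 largest and 12 smallest ratios above the lower quartile of level, and dotted lines mark 2-fold. miR-205-5p and miR-937-5p are the only points above the upper line, and no point lies below the lower line.

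Lower in the induced array, miR-4521 had the smallest ratio, -0.77 ± 0.058, and its deposited value was 163 in the not induced and 42.4 in the induced array, a 3.86-fold difference. With the planned background column its log2 ratio was 0.06, with the spot under the column on the not induced array. miR-1285-3p followed with -0.67 ± 0.072, a 1.31-fold difference in the deposited values, and 0.23 with the planned column. The remaining 10 of the 12 smallest ratios ranged from -0.56 to -0.43: miR-3175, miR-187-5p, miR-3648, miR-7114-5p, miR-5739, miR-487b-3p, miR-3907, miR-4667-5p, miR-4502 and miR-874-5p. In the simulated arrays an unchanged miRNA reached a ratio of 0.55 by size. The deposited values of miR-3175, the farthest apart of these 10, differed by 1.17-fold. miR-187-5p, for example, stood at 1637 units on the not induced and 1518 on the induced array, and its deposited values differed by 1.12-fold. Their lower ratios are relative to the other bright miRNAs, which were brighter on the induced array before scaling by a median log2 ratio of 0.41 over the brightest 333. miR-3648 changed sign, to 0.01, with no scaling between the arrays. With the planned background column all of these 10 but miR-187-5p (-1.66) and miR-5739 (-0.15) stood above 0, although miR-3175, miR-7114-5p, miR-3907 and miR-874-5p did so with a spot under the column on the not induced array. Among miRNAs detected on the not induced array only, the brightest were miR-139-5p, miR-4493 and miR-4654. The deposited value of miR-139-5p, 48.8, was at least 5.77-fold above the lowest value given on the induced array. On the induced array only, miR-373-5p was brightest, at least 7.32-fold above the lowest deposited value on the not induced array, followed by miR-205-3p and miR-548q (at least 3.30-fold). On the offset scale the bounds were at least 1.24-fold for miR-139-5p and at least 1.23-fold for miR-373-5p. None of these bounds includes spot error, and they belong to the brightest miRNAs detected on 1 array. Under the planned background column miR-139-5p was at 0.01, miR-373-5p at 0.0013, miR-205-3p at -0.0037 and miR-548q at 0.0040, so that none of these differences was seen there.

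**Figure D2:**
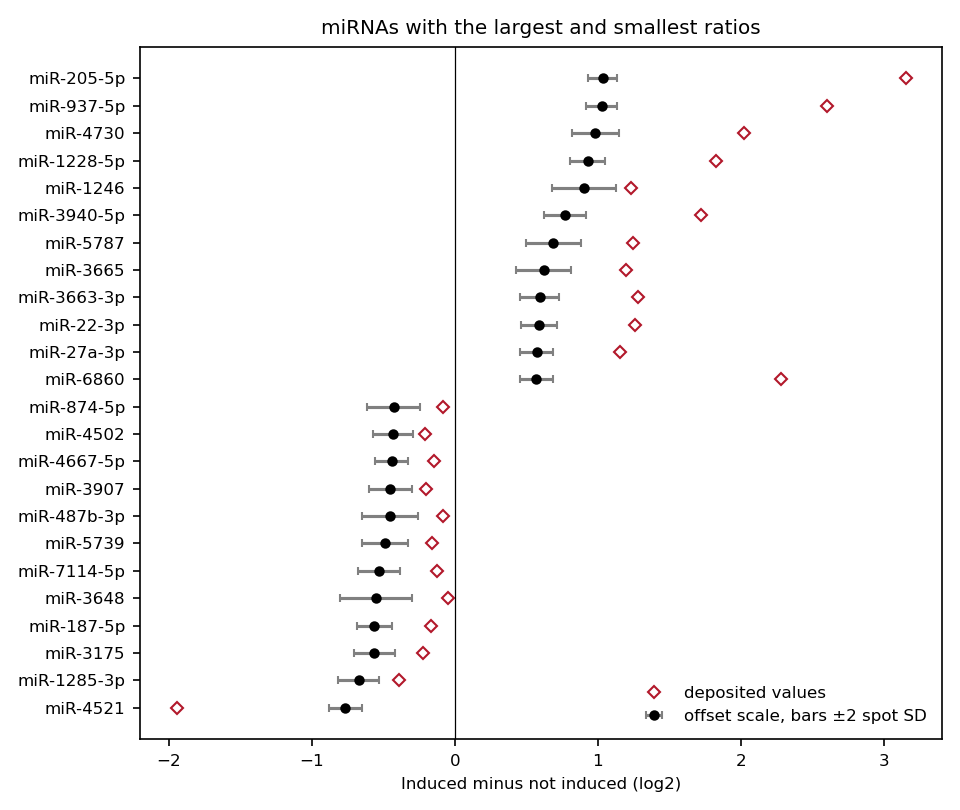
Log2 ratio of the induced over the not induced array (horizontal axis) for the 12 largest and 12 smallest ratios; filled points are the offset scale with bars of 2 SDs from repeated control spots, open diamonds the authors' deposited values. Every miRNA shown keeps its side of 0 on both scales, although miR-3648 does not with no scaling and several do not with the planned background column, and the deposited log2 ratios of the lower miRNAs other than miR-4521 and miR-1285-3p lie between -0.22 and -0.05.

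The miR-200 family, epithelial miRNAs that target ZEB1 and ZEB2, was higher as a group in the induced array. All 9 of its probes were detected on both arrays, with a median log2 ratio of 0.16, at percentile 99.6 of 10000 random lists of the same size matched on level. 4 members were higher by more than 2 spot SDs and none was lower. Of all 1330 miRNAs detected on both arrays, 155 were higher and 163 lower by this rule. The tallies of this and the following lists are to be read beside that share. miR-200a-3p had a log2 ratio of 0.24 ± 0.071 and miR-429 of 0.20 ± 0.054, and their deposited values were 1.84-fold and 1.85-fold higher. miR-200b-3p (0.20), miR-200c-3p (0.19) and miR-141-3p (0.16) lay close to them, while the passenger arm miR-200a-5p was at -0.08 and 1.59-fold lower in the deposited values. Over 5 other scalings the percentile ranged from 98.1 to 99.6. It was 95.1 with the background subtracted and no offset, inside the random range, and with the planned background column the median was -0.0041 at percentile 30.2. There the spots of miR-200c-3p, miR-200a-3p and miR-141-3p lay under the column on both arrays, and that of miR-200b-3p on the induced array. These members thus had no signal above that background to compare.

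The miR-23/27/24 clusters were the other list above the random range, with a median log2 ratio of 0.12 over 8 detected members, at percentile 98.4. miR-27a-3p (0.57), miR-23b-3p (0.31), miR-23a-3p (0.31) and miR-24-3p (0.22) were higher by more than 2 spot SDs. The other 4 were within that range. Its percentile was at least 99.5 under each of the 5 other scalings, and 93.5 with the planned background column, 91.9 among miRBase entries numbered under 1000 and 82.2 with no detection filter. The spot of miR-23b-3p lay under that column on both arrays, and that of miR-23a-3p on the induced array.

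The miR-17-92 cluster and its paralogs, which are linked to proliferation, lay at the other end. Their median log2 ratio over 20 detected members was -0.13, at percentile 0.02, and 9 members were lower by more than 2 spot SDs and none higher. miR-93-5p was at -0.40 ± 0.111 and miR-106b-5p at -0.33 ± 0.109, followed by miR-19b-3p at -0.30 and miR-17-5p at -0.29. The deposited values of miR-93-5p and miR-106b-5p were 1.01-fold and 1.05-fold higher in the induced array, so that their lower ratio is again relative to other miRNAs of like brightness. The opposite arm miR-106b-3p was lower on both scales, at -0.27 ± 0.051 and 1.78-fold lower in the deposited values. The position of the whole list depended on the scaling. Under 5 other scalings its percentile ranged from 7.12 to 29.7 and the median from -0.06 to 0.17, above 0 in 4 of them. It was also inside the random range with the background subtracted (percentile 6.47), with the planned background column (5.75) and with no detection filter (8.55). With that column miR-93-5p was at 0.37 and miR-106b-5p at 0.67. The spots of miR-106b-5p and miR-17-5p lay under the column on the not induced array. These 3 lists stood outside the central 95% of random lists of 17 with 3 or more detected members, where 0.85 would be outside by chance if members varied independently. Members of these 3 lists are encoded in shared clusters or near-identical in part, so that they need not vary independently and the chance number may be higher.

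Among 18 detected miRNAs reported as regulated by p53, 8 were higher by more than 2 spot SDs and 1 lower, and the median of 0.03 lay at percentile 96.5. The higher ones included miR-1246 and 3 of 4 miR-29 probes, with miR-29b-3p at 0.33 ± 0.061, miR-29a-3p at 0.28 and miR-29c-3p at 0.27, whose deposited values were 2.07-fold, 2.04-fold and 2.01-fold higher. miR-29c-5p was at 0.02 ± 0.052. miR-194-5p was at 0.29 and miR-192-5p at 0.20, while miR-34a-5p, a direct p53 target, was at 0.03 ± 0.046. Under the 5 other scalings this list lay at percentile 99.0 or above. It was also above the random range with the background subtracted (percentile 99.7, median 0.32), at 3 SD (99.95) and over the brighter part of the miRNAs (99.9). It was inside with the planned background column (73.0), among entries numbered under 1000 (85.0) and with no detection filter (88.6). The spot of miR-107 lay under that column on both arrays, and that of miR-1246 on the not induced array.

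Of 30 detected miRNAs linked to p63 in earlier work, 1 was higher by more than 2 spot SDs, miR-205-5p, and 7 were lower. Of all 1330 detected miRNAs, 155 were higher and 163 lower by this rule. The list median lay at percentile 68.2. No expected direction was set for the members, so that changes in opposite directions would not move this median. The lower tally depends on the scale, since 4 of these 7 were higher in the deposited values, miR-181a-5p by 1.24-fold, miR-20b-5p by 1.17-fold, miR-17-5p by 1.14-fold and miR-193a-3p by 1.11-fold. The list stood above the random range with the planned background column, at percentile 98.4 and a median of 0.0094. The spots of miR-17-5p, miR-130b-3p and miR-193a-3p lay under that column on the not induced array. miR-203a was at 0.15 ± 0.085, miR-130b-3p at -0.15 ± 0.051 and miR-193a-3p at -0.20 ± 0.050. miR-34c-5p was not detected on either array, and miR-34c-3p was at -0.03. Markers of basal breast cells, apart from miR-205-5p, showed no common shift. Their list lay at percentile 67.0, miR-221-3p was at -0.01 ± 0.052, and neither arm of miR-222 was detected. Of 26 detected luminal markers 7 were higher and 2 lower by more than 2 spot SDs, from miR-29c-3p at 0.27 to miR-342-3p at -0.38 ± 0.079, which was equal on the arrays in the deposited values, with the list at percentile 37.6. Over the brighter part of the detected miRNAs the luminal list stood above the random range, with a median of 0.14 at percentile 98.8.

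Several other lists held single members that stood apart while the list median was within the random range on the main scale, although some of these medians left it under other settings. In the list linked to epithelial-mesenchymal transition, at percentile 70.7, miR-22-3p was joined by miR-21-5p, at 0.46 ± 0.097 and 1.70-fold higher in the deposited values, whereas miR-21-3p was at -0.23 ± 0.053, with deposited values of 185 and 184. With the planned background column miR-21-5p was at -0.20. The let-7 family was at percentile 82.9, with let-7f-5p at 0.32 ± 0.109 and miR-98-5p at 0.18 ± 0.067, and the miR-30 family at percentile 77.7, with miR-30b-5p at 0.33 and miR-30e-5p at 0.26. The let-7 list stood above the random range under 4 other scalings, at percentile 99.7 with median scaling, 99.6 with 75th percentile scaling, 99.8 with no scaling and 99.8 with spike control scaling. Its median was 0.02 on the main scale and from 0.23 to 0.51 under these. The miR-30 list did so with no scaling (98.3) and spike control scaling (98.1). In the list of the miR-15, miR-16, miR-103 and miR-107 families, at percentile 25.2, miR-15b-5p was at -0.37 ± 0.079 (0.01 with no scaling) and miR-107 at 0.29 ± 0.081. This list was at percentile 98.0, above the random range, with the planned background column, although the spots of miR-15b-5p and miR-107 lay under it on both arrays. The imprinted 14q32 cluster was at percentile 7.85, with 5 of 28 members lower, among them miR-487b-3p at -0.45 and miR-134-3p at -0.30, and none higher. It stood below the random range with no detection filter (percentile 2.12), among entries numbered under 1000 (2.22) and over the brighter part of the miRNAs (0.33, with a median of -0.13 against -0.02 on the main scale). Its median was above 0, at 0.10, in the deposited values. The hypoxia-responsive miR-210-3p was at 0.05 ± 0.058 and miR-210-5p at -0.07 ± 0.055. Entries overlapping other RNA classes were at percentile 64.2 and ran from miR-3648 at -0.55 to miR-1246 at 0.90, with the saturated miR-4454 counted at 0.

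Markers of other cell types lay within the spot error. No detected member of the haematopoietic list (5 detected of 11), the mesenchymal and muscle list (9 of 16), the neural and liver list (3 of 8) or the placental C19MC cluster (26 of 49) differed by more than 2 spot SDs. Their largest ratios by size were 0.08 for miR-150-3p, 0.08 for miR-199a-5p, -0.08 for miR-9-3p and -0.08 for miR-526b-3p, all close to the detection limit, where the offset leaves little room for a ratio. In the deposited values miR-199a-5p was 2.47-fold and miR-150-3p 1.73-fold higher, and miR-9-3p was 1.75-fold, miR-526b-3p 1.84-fold and miR-520h 2.06-fold lower.

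**Figure D3:**
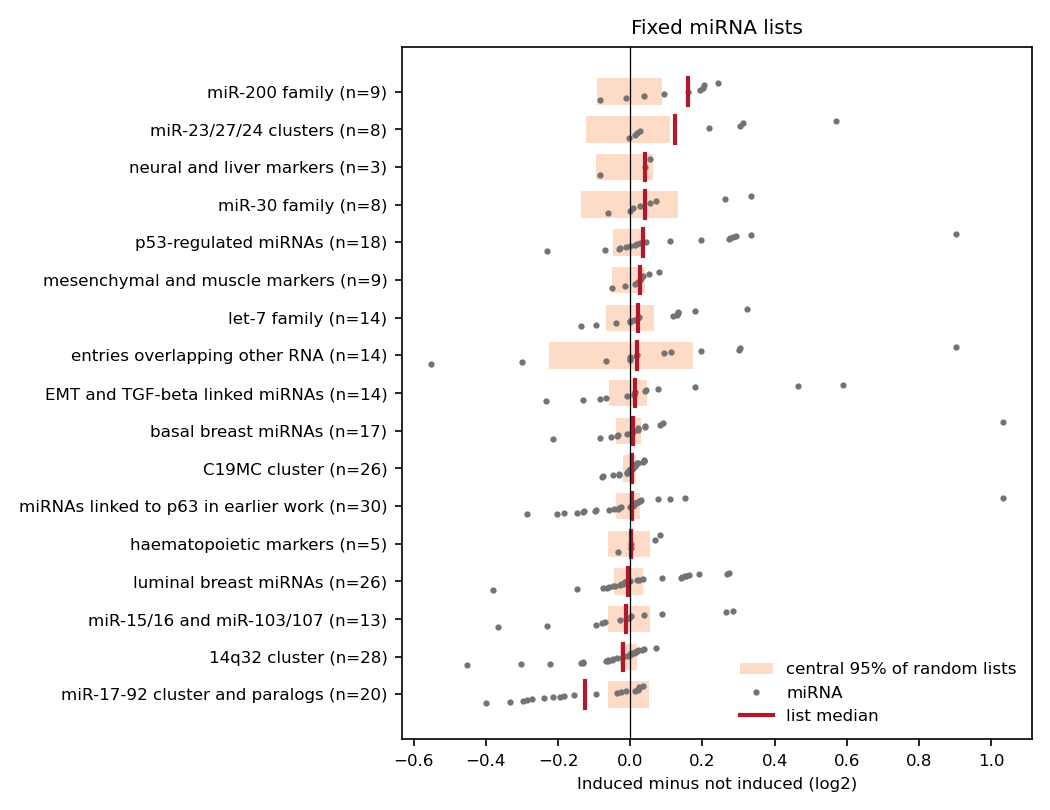
Log2 ratio of the induced over the not induced array (horizontal axis) for the detected members of 17 miRNA lists; points are miRNAs, vertical bars the list medians, and shaded boxes the central 95% of the medians of 10000 random lists matched on size and level. The miR-200 family and the miR-23/27/24 clusters lie to the right of their boxes, and the miR-17-92 cluster with its paralogs lies to the left, which it does not under 5 other scalings. With the planned background column none of these 3 lists lies outside its box, but each holds members with a spot under the column on at least 1 array.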

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

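The choice of the 3 patterns weighed here, the 1.5-fold limit for control probes, and every test but that of the adjacent spots came after the results were seen.

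Signal appeared in probes outside the comparison. Of 22 probes named S-Probe with 1 spot each, whose targets the files do not name, 15 were detected on both arrays and 14 of these were higher on the induced array after blank subtraction. 7 were at least 1.5-fold higher: S-Probe1002 by 1.62-fold, S-Probe1006 by 1.57-fold, S-Probe1007 by 1.54-fold, S-Probe1008 by 1.88-fold, S-Probe1009 by 1.95-fold, S-Probe1013 by 1.51-fold and S-Probe1016 by 1.71-fold. The median over the 15 was 1.37-fold, so these are the largest of a general rise. The folds are not scaled between the arrays.

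The ratio of miR-205-5p was weighed against technical explanations. The 5 adjacent spots showed no common brightening, with a median log2 ratio of spot medians of 0.0103 and a highest value of 0.30, against 1.45 for miR-205-5p. No blank was subtracted, so that stronger local hybridisation would change the ratio of dim neighbours little, and their brightness is not given here. The background column at miR-205-5p was 27.6 units on the not induced and 94.6 on the induced array. A fault of 1 spot cannot be told apart from a change of the miRNA. miR-205-3p, which sits in another block, was higher by 3.28 SDs of repeated dim control spots after blank subtraction, but it lay near the detection limit, was detected on 1 array only and had a log2 ratio of -0.0037 with the background column of the scanner files. The choice of background also stays open, since the lowest log2 ratio over 4 other background settings was 0.048, with that column. Before the offset and the quantile step, the excess of the miR-205-5p spot over the column was 1.76-fold higher on the induced array. An effect of doxycycline itself cannot be told apart from one of ΔNp63α, because 0 of the arrays analysed here hold treated cells without the construct, and the difference between single cultures also stays open.

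The lower position of the miR-17-92 cluster and its paralogs may come from the scaling, since its percentile rose to 29.7 when the arrays were scaled by the median in place of quantiles. Cross-hybridisation among the near-identical members of the miR-17 seed family also stays open. The 6 detected members from hairpins of other families than miR-17 and miR-18, 4 of them lower, lay at percentile 10.7, with a median log2 ratio of -0.10. An effect of the induction is untested beside these.

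Before scaling, 290 of the brightest 333 miRNAs (87.1%) were higher on the induced array. The mean log2 ratio of the spike controls was 0.0401 ± 0.024 (SE, 16 spots per array) against a median of 0.41 for these miRNAs. The spots repeat only 2 spikes, at -0.0043 and 0.084, and the SE does not cover differences between arrays. A brighter scan or hybridisation is argued against only at the level of the spikes, with means of 5061 to 6062 units. Only 16 and 21 miRNA probes exceeded 1000 units, and how the scans were joined is not given. A difference in brightness at lower levels thus stays open. Blank spots had a background median of 19.1 and 26.1 units and a spot median of 37.1 and 36.1. When the spikes were added is not given in the sources used here. More small RNA in the labelled sample cannot be told apart from a broad rise of miRNAs in the cells. The ratios scattered with an SD of 0.48 around the shift, which both would allow.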

How the results depend on the processing

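The local background column had been the planned main correction and became an alternative after the files were seen, when the blank mean replaced it. Spike control scaling was added after the data were seen. The others were fixed before, although those with a background correction were run with the blank mean. The number of detected miRNAs was 1057 at 3 SD and 480 among entries numbered under 1000, against 1330. The 2 miRNAs at least 2-fold higher became 33 with the background subtracted and no offset, 4 with no background correction, 8 with an offset of 10, 6 with median scaling, 4 with 75th percentile scaling, 9 with no scaling, 9 with spike control scaling, 77 in the deposited values, 4 with the local background column and 10 at 1.5-fold. The 0 at least 2-fold lower became 35 with the background subtracted, 1 with an offset of 10, 16 in the deposited values, 4 with the local background column and 2 at 1.5-fold. A smaller offset raises these counts by construction, since the offset compresses ratios. The number of lists outside the random range was 3, and became 4 with median scaling, with 75th percentile scaling and at 3 SD, 5 with no scaling, 5 with spike control scaling and 6 in the brighter part of the miRNAs. It was 2 with the background subtracted, 2 with the local background column, where neither list was among the 3, and 2 with no detection filter. The median of the miR-17-92 list turned to 0.013 with median scaling, 0.065 with no scaling, 0.17 in the deposited values and 0.047 with spike control scaling; the cause was not tested beyond the weighing above. With the local background column, which removes signal of bright spots, the miR-200 median turned to -0.0041, and miR-937-5p to -0.019, miR-5787 to -0.17, miR-3665 to -0.069, miR-22-3p to -0.16, miR-4521 to 0.062 and miR-1285-3p to 0.23, while miR-205-5p stood at 0.048. The spots of miR-5787 and miR-4521 lay under the column on 1 array. Those of miR-200c-3p, miR-200a-3p and miR-141-3p lay under it on both arrays, and that of miR-200b-3p on the induced array. No other named miRNA past 1.5-fold reversed under any setting. The median log2 ratio of the detected miRNAs was 0.00 in the main values and 0.21 in the deposited values. Over the brightest 333 it was 0.35 in the deposited values, so that deposited folds include a shift that depends on level. No paired analysis was possible because each group is 1 array, and leaving out an array leaves no comparison. Signal over background limits most results, since the median detected spot stood at 44.2 and 43.6 units against detection limits of 39.3 and 38.7. Negative Control 3 stood above these limits, at 43.4 and 42.6 units.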

Other observations

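The tests of neighbours and of arms were set before their summary values were seen, although single values had been; the pairs named here and the check without shared lists were chosen afterwards.

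On the quantile-normalised scale, miRNAs encoded next to each other tended to have like ratios. miR-182-5p and miR-96-5p were slightly higher, at 0.14 and 0.15, although miR-183-5p of the same cluster was at -0.00051. miR-425-5p (0.14) and miR-191-5p (0.19) were also slightly higher. miR-192-5p and miR-194-5p were at 0.20 and 0.29, and miR-99a-5p and let-7c-5p both at 0.13. miR-15b-5p and miR-16-5p were lower together, at -0.37 and -0.23, although miR-16-5p was 1.20-fold higher in the deposited values. miR-642b-3p and miR-642a-3p went apart, at 0.22 and -0.28. The hypothesis, written before its test, was that miRNA genes within 10 kb of each other differ less than random pairs. Gene positions came from the RefSeq table of assembly GRCh38.p14, used only to find neighbours, in which 322 of the 333 brightest miRNAs matched a gene by name. Over 69 neighbouring pairs of different hairpins the median absolute difference of log2 ratios was 0.13, against 0.27 in level-matched random pairs, at percentile 0 of 10000 draws. Pairs share members and some are near-identical in sequence. The 15 pairs that share no fixed list, a check added after this result, also had a median difference of 0.13, at the 1.59th percentile.

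The companion hypothesis, that the arms of 1 hairpin share the sign of their ratios, could not be decided. Of 312 hairpins with both arms detected on both arrays, 164 (52.6%, exact 95% interval 46.9 to 58.2) had arms of the same sign. The criterion set beforehand counted an interval that includes an even share against the hypothesis, and was dropped after the values were seen. Most of these ratios lie within the spot error, where noise can set the sign: of the 1330 miRNAs detected on both arrays, 155 were higher and 163 lower by more than 2 spot SDs. Of 17 hairpins with both arms beyond 2 spot SDs, 7 had arms of the same sign, miR-22 among them (41.2%, exact 95% interval 18.4 to 67.1). The arms were compared on the quantile-normalised scale only, and signs can depend on the scaling: miR-21-3p was at -0.23 on this scale and at 0.025 with no scaling, beside miR-21-5p at 0.46 and 0.80.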
